A study of Mus musculus with 19 samples.

How the data were processed

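RNA from 9 wild-type and 10 HSALR samples of EDL muscle was labelled with biotin and measured on 1-colour Affymetrix arrays, 1 array per sample, per the labels' protocols. The deposited values are linear signal intensities of 45101 probe sets per array, and GCOS 1.4 is named in the submitters' processing notes. The algorithm, the scaling target and any filter are not given in the sources used here. All deposited intensities were above 0, and their trimmed mean (after removing the lowest and highest 2% of values) ranged from 157 to 244 between arrays, so the arrays had not been brought to 1 common trimmed mean. The design fixed before the data were examined kept the scaling as deposited, and quantile normalization and centring of each array on its median were run beside it. The median signal of each array lay between 39.7 and 71.9. For arrays of this kind no count of molecules is known, and the number of arrays is among the limits of the precision.

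The values were used as log2(value + 16), so a fold change is on that scale and understates the change of dim genes. The 64 control probe sets were left out, and probe sets were kept when their mean log2 value over all 19 samples was at or above the median of that mean (6.09), which left 22519. Of the probe sets other than controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 are unnamed here. For 34741 of them the symbol was taken from the current mouse gene table through the Entrez identifier, and no gene was named from a probe set with several symbols. Among the tested probe sets 19322 had 1 gene symbol, and a gene was counted through its brightest probe set, the one with the highest mean over all samples. No genome build is stated for the values, so no coordinates are given.

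HSALR was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, 2-sided) with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. Errors of log2 folds are standard errors from this fit. Fixed lists of genes, 34 in all, were tested with limma's camera with the inter-gene correlation estimated per list, on 1 probe set per gene, for the 32 lists with 3 or more measured members apart from the sex-linked genes, which served as a check and of which 0 of 4 passed in limma and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. Camera with a preset correlation of 0.01 and fry were run beside it. Differences between probe sets of 1 gene were tested with limma's diffSplice, with probe sets in the place of exons. Values per sample were compared between groups with an exact permutation test that enumerated all 92378 splits of 19 samples into 9 and 10, in place of the random draws that the design named, with the same statistic.

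Named genes followed a rule fixed in the design: the 12 largest rises and the 12 largest falls among genes past the threshold, 10 genes whatever their result, up to 4 members of each list past the threshold with the smallest p, and the 5 genes with the smallest p for a difference between probe sets. This gave 75 genes. Alternatives fixed at the same time were pseudocounts of 1 and 64, no filter or only the 11260 brightest probe sets, both other scalings, the replicate number as a block, array weights, another variance model, the 3'/5' ratio of the control probe sets as a covariate, a test against a fold of 1.2, other list tests and leaving out each of the 19 samples. Leaving out HSALR replicates 9 and 10, averaging them, and leaving them out with quantile normalization were added after the data were seen. All of these fits used the same 19 samples unless stated, except that the replicate block left out HSALR replicate 10, whose number no wild-type sample has.

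The fits were tested on simulated data made from the real means and residual SDs of the 22519 probe sets, without correlation between them, with 50 probe sets changed at each of 4 folds. In this simulation of HSALR against wild type, 31 of 50 changes of 1.5-fold were found, 48 of 50 of 2-fold, 50 of 50 of 3-fold and 50 of 50 of 4-fold, and 12 unchanged probe sets were called. Of 32 lists, the 1 that was shifted, oxidative phosphorylation, was called, and so was 1 other, the tricarboxylic acid cycle, which shares genes with it. In the real data the estimated correlation of the oxidative phosphorylation list was 0.671. The simulation, which had none, therefore does not show what the list test can find in the real data. Of 50 genes with 1 probe set changed 2-fold, among 4782, 41 were called, with 4 other genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.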

Results

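Gene expression was measured in the extensor digitorum longus (EDL), a fast muscle of the lower hind leg, of FVB mice aged 19 weeks. Wild-type mice were compared with HSALR mice, which carry a human skeletal actin transgene with a long CTG repeat and serve as a model of myotonic dystrophy. There were 9 wild-type and 10 HSALR samples, each measured on 1 Affymetrix array, and this number of arrays limits the precision of every value. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The median log2 signal of the tested probe sets ranged from 7.30 in HSALR replicate 5 to 7.96 in HSALR replicate 8. It averaged 7.65 ± 0.12 (SD, n = 9) in wild type and 7.70 ± 0.22 (SD, n = 10) in HSALR, a difference that did not pass (exact permutation p = 0.523, 2-sided, adjusted p = 0.572 over 4 quality measures). The log2 3'/5' ratio of the actin control probe sets was lower in HSALR by 0.10 (exact permutation p = 0.0098, adjusted p = 0.0392). That of the Gapdh control probe sets differed by 0.006 (exact permutation p = 0.572, adjusted p = 0.572). The mean of both ratios was -0.11 ± 0.04 (SD, n = 10) in HSALR and -0.06 ± 0.05 (SD, n = 9) in wild type (exact permutation p = 0.0295, adjusted p = 0.059). HSALR replicates 9 and 10 resembled each other more than any other pair, with a Spearman correlation of 0.978 across probe sets, against a highest value of 0.953 to 0.969 for each other sample.

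The comparison of HSALR with wild-type muscle asked which transcripts differ in EDL muscle that carries the repeat. Mybph, a myosin-binding protein of the thick filament, rose 10.8-fold in HSALR muscle (log2 fold 3.43 ± 0.31, SE, n = 10 against 9). Sln, which encodes sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum, rose 8.28-fold (log2 fold 3.05 ± 0.25). Kcnab1, a beta subunit of voltage-gated potassium channels, fell 7.03-fold (log2 fold -2.81 ± 0.13), and Dkk3, a secreted protein of the dickkopf family, fell 6.12-fold (log2 fold -2.61 ± 0.32). In Mybph and Sln all 10 HSALR samples lay above every wild-type sample, and in Kcnab1 all 10 lay below, as did 9 of 10 in Dkk3. Of 22519 probe sets tested with limma, 645 rose and 495 fell at a false discovery rate of 0.05. With 1 probe set per gene, 359 of 11533 genes rose and 266 fell. Folds are on the scale of log2(value + 16), which understates the change of dim genes. A change of at least 1.5-fold was seen in 324 probe sets that rose and 190 that fell.

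Among the other large rises, Cpne2, a calcium-dependent phospholipid-binding copine, rose 7.15-fold (log2 fold 2.84 ± 0.16, limma adjusted p = 1.31e-10). Eda2r, a receptor of the tumour necrosis factor receptor family, had a log2 fold of 2.41 ± 0.13 (limma adjusted p = 8.16e-11), and Cilp, a matrix protein first described in cartilage, of 2.35 ± 0.14 (limma adjusted p = 2.92e-10). The metalloproteinase genes Mmp13 and Mmp3 rose by 3.50 ± 0.89 and 2.43 ± 0.65 on the log2 scale, with limma adjusted p of 0.0214 and 0.0281, and only 7 of 10 HSALR samples lay above all wild-type samples. Their log2 folds were 2.22 and 1.56 without HSALR replicates 9 and 10, in which Mmp13 reached log2 signals of 12.9 and 13.1. The wild-type mean of Mmp13, 4.38, lay near the floor of 4 on this scale, and its call was lost with a pseudocount of 64 (adjusted p = 0.0586), as was that of Mmp3 without a filter (0.0613) and with another variance model (0.0609). The protease inhibitor gene Serpinb1a rose by 2.02 ± 0.26 and Rrad, a small GTPase of muscle, by 1.83 ± 0.27. Ankrd1 and Csrp3, a muscle ankyrin repeat protein and the muscle LIM protein, rose by 1.79 ± 0.28 and 1.78 ± 0.25. Rian, a noncoding RNA of an imprinted cluster, rose by 1.90 ± 0.22, and its neighbour in that cluster, Meg3, by 1.61 ± 0.13. Dimmer probe sets of Rian had log2 folds of 1.91 ± 0.15 and 0.53 ± 0.19, and the latter did not pass (limma adjusted p = 0.1).

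**Figure D1:**
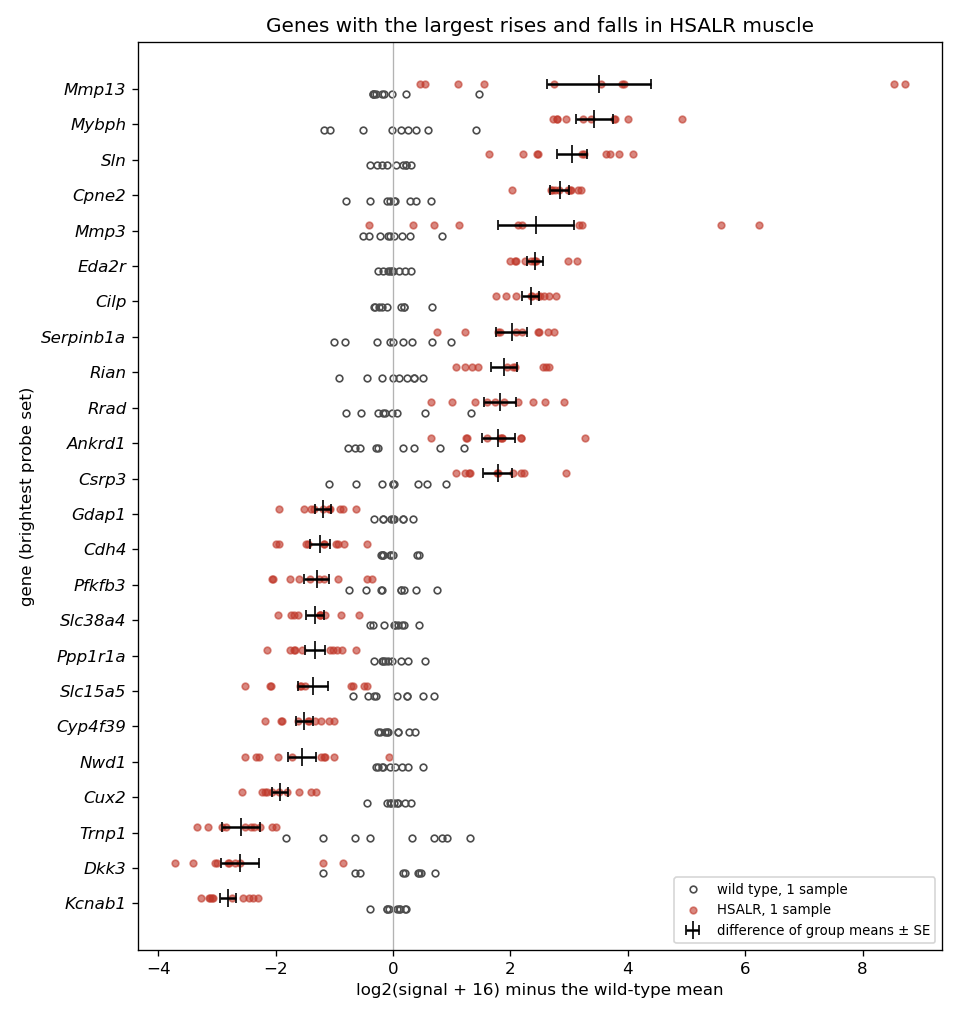
Log2(signal + 16) of the 12 genes with the largest rises and the 12 with the largest falls, each sample drawn as its distance from the wild-type mean (grey circles, 9 wild-type samples; red points, 10 HSALR samples), with the difference of the group means ± SE in black. In Kcnab1 all 10 HSALR samples lie below every wild-type sample, while the rise of Mmp13 is led by 2 HSALR samples.

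The falls were led by genes of several kinds. Trnp1, a nuclear protein, fell 6.03-fold (log2 fold -2.59 ± 0.33), Cux2, a homeodomain transcription factor, fell 3.81-fold (log2 fold -1.93 ± 0.14), and Nwd1 had a log2 fold of -1.55 ± 0.24. The cytochrome P450 gene Cyp4f39 fell by 1.51 on the log2 scale, with an SE of 0.14. Ppp1r1a, a regulatory subunit of protein phosphatase 1, had a log2 fold of -1.34 ± 0.17. The same log2 fold of -1.34 was measured for Slc38a4, an amino acid transporter, and Slc15a5, of a family of peptide transporters, had -1.37 ± 0.26. Pfkfb3, which makes an activator of glycolysis, had a log2 fold of -1.31 ± 0.22, Cdh4, a cadherin, of -1.24 ± 0.17 and Gdap1, a protein of the mitochondrial outer membrane, of -1.20 ± 0.14. The 2 probe sets of Pfkfb3 changed by different amounts (limma diffSplice adjusted p = 0.0425), and its value here is from the brighter.

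The counts and their split depended on how the arrays were scaled. After quantile normalization 1484 probe sets were higher and 1856 lower, and with each array centred on its median 1364 were higher and 1573 lower. With 1 probe set per gene, 817 of 11533 genes rose and 968 fell after quantile normalization, the background for the list counts in that setting. Of the probe sets called as deposited, 1135 of 1140 were also called after quantile normalization in the same direction and 0 in the opposite one. The total was 2067 (1562 higher, 505 lower) without HSALR replicate 5, 2878 (2278 higher, 600 lower) with array weights, 2169 (1705 higher, 464 lower) with the 3'/5' ratio as a covariate and 176 (106 higher, 70 lower) when a fold over 1.2 was tested. For changes of at least 1.5-fold the split was 990 higher and 218 lower with that covariate, 600 and 179 without HSALR replicate 5, 522 and 163 with array weights and 327 and 270 after quantile normalization.

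The gene lists were fixed before the data were examined, and each count of members is followed by the count adjusted over the list alone. Among 14 slow fibre proteins, Csrp3 and Ankrd2, a stretch-responsive ankyrin repeat protein (log2 fold 1.27 ± 0.28), rose and the myosin gene Myh7b fell (log2 fold -0.53 ± 0.15), with the same counts adjusted over the list alone. Of 16 fast fibre proteins, Mylk2, the skeletal myosin light chain kinase, fell (log2 fold -0.73 ± 0.16) and was also the only one adjusted over the list alone; after quantile normalization 5 fell. Of 7 myosin heavy chain genes only Myh7b fell, also adjusted over the list alone. Myh1, Myh2 and Myh4, the fast myosin heavy chains, had log2 folds of 0.04 ± 0.07, -0.01 ± 0.10 and 0.01 ± 0.07, and those of Myh1 and Myh4 took the opposite sign with arrays centred on their median. Myh7, the slow myosin heavy chain, had a log2 fold of -0.73 ± 0.66 (limma adjusted p = 0.574), with an SD of 1.64 among wild-type samples and 1.66 among HSALR samples. It was -0.39 without HSALR replicate 9 and -0.22 without replicates 9 and 10.

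Among 28 genes of excitation-contraction coupling and calcium handling, 3 rose and 3 fell (3 and 5 adjusted over the list alone, and 3 and 9 after quantile normalization). Trdn, which rose only at a probe set other than its brightest (log2 fold 1.08 ± 0.13, limma adjusted p = 1.44e-05), is not counted there. Besides Sln, Camk2d, a calcium/calmodulin-dependent kinase (log2 fold 0.75 ± 0.12), and Cacng1, a subunit of the muscle calcium channel (0.60 ± 0.10), rose. Mrln, which encodes myoregulin, another small inhibitor of the calcium pump, fell (log2 fold -0.71 ± 0.11). Camk2a (-0.45 ± 0.13) and Jph2 (-0.43 ± 0.12), named after their values were seen, also fell. Their calls were lost without HSALR replicates 9 and 10 (log2 folds -0.45 and -0.39, adjusted p = 0.0829 and 0.0972), but not when quantile normalization was applied as well (adjusted p = 0.00525 and 0.00336). None of 18 membrane ion channel and pump genes passed in limma or adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. Clcn1, the muscle chloride channel lost in myotonia, had a log2 fold of -0.50 ± 0.15 that missed the threshold (limma adjusted p = 0.0602). It passed after quantile normalization (log2 fold -0.57, limma adjusted p = 0.00749) and with arrays centred on their median (0.00778). It passed more narrowly with a pseudocount of 64 (0.0474), with another variance model (0.0422) and among the 11260 brightest probe sets (0.0393). Without HSALR replicates 9 and 10 it missed the threshold (0.146), as in 15 of 19 fits without 1 sample. Over the settings that kept all samples, its adjusted p ranged up to 0.199, with array weights. Of 27 genes for MBNL, CELF and other RNA-binding proteins, Rbfox1, a splicing factor, fell (log2 fold -0.44 ± 0.09), also adjusted over the list alone, and after quantile normalization 2 rose and 2 fell. Mbnl1, Mbnl2 and Celf1, splicing regulators studied in myotonic dystrophy, had log2 folds of 0.22 ± 0.10, 0.20 ± 0.10 and 0.16 ± 0.09, with limma adjusted p of 0.22, 0.237 and 0.286. These values are from the brightest probe sets. The 4 probe sets of Celf1 differed (limma diffSplice adjusted p = 0.00464), with log2 folds from -0.31 ± 0.11 to 0.38 ± 0.12. The lowest and highest missed the threshold as deposited (limma adjusted p = 0.1 and 0.0587) and passed after quantile normalization (0.00138 and 0.018). Of 32 genes known to be spliced by MBNL in muscle, 1 rose (Camk2d), also adjusted over the list alone, against 1 higher and 8 lower after quantile normalization.

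The transgene and the human disease gene were read through Acta1 and Dmpk, although it is not known here whether the mouse probe set for Acta1 reads the human transgene. Acta1, skeletal muscle actin, had a mean log2 signal of 13.6 in both groups (log2 fold 0.03 ± 0.07, limma adjusted p = 0.871), and the sign turned after quantile normalization (-0.01) and with arrays centred on their median (-0.03). The signals of Acta1, Myh1 and Myh4 lay near the highest of each array (13979 to 17163 between arrays), where changes can be compressed, so an absence of change is not read from them. Dmpk, the kinase gene with the repeat in the human disease, had a log2 fold of -0.05 ± 0.14 (limma adjusted p = 0.878).

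Genes of energy metabolism changed in small numbers. None of 58 oxidative phosphorylation genes passed in limma, also adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05, and none of 21 tricarboxylic acid cycle genes, with 0 higher and 1 lower. Mdh2, of the tricarboxylic acid cycle list, fell at a probe set other than its brightest (log2 fold -0.40 ± 0.08, limma adjusted p = 0.00334). Of 22 genes of glycolysis and glycogen, Fbp2, a muscle fructose bisphosphatase, rose (log2 fold 0.60 ± 0.16), and Gpd1, glycerol phosphate dehydrogenase (-0.50 ± 0.10), and Phkb, a subunit of phosphorylase kinase (-0.31 ± 0.09), fell. The call of Phkb (limma adjusted p = 0.0498) was lost in 16 of 19 fits without 1 sample. With the 3'/5' ratio as a covariate Fbp2 (log2 fold 0.41, limma adjusted p = 0.14) and Phkb (0.062) missed the threshold. So did Cd36 (0.0575) and Tbc1d4 (0.0583), of the lists that follow. Adjusted over the list alone 1 rose and 4 fell, and after quantile normalization 1 rose and 7 fell. Cd36, a fatty acid transporter, was the only one of 22 fatty acid genes to rise (log2 fold 0.37 ± 0.11), also adjusted over the list alone. It did not pass after quantile normalization (adjusted p = 0.0871), where 0 rose and 3 fell. Among 9 polyamine genes, Sat1, which acetylates polyamines, the related gene Sat2, and Azin1, an antizyme inhibitor, rose by 0.77 ± 0.17, 0.41 ± 0.10 and 0.44 ± 0.13. Smox, spermine oxidase, fell (log2 fold -0.94 ± 0.15), and the counts were the same adjusted over the list alone. Of 26 genes of insulin and growth factor signalling, Tnfrsf12a, the receptor of the cytokine TWEAK, rose 3.40-fold (log2 fold 1.76 ± 0.26). The 3 that fell were Prkab2, a subunit of the AMP-activated kinase (-0.73 ± 0.13), Igfbp5, a binding protein of insulin-like growth factors (-0.66 ± 0.16), and Tbc1d4, a regulator of glucose transport (-0.42 ± 0.11). Adjusted over the list alone 2 rose and 5 fell, and after quantile normalization 2 rose and 6 fell.

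In the lists for protein folding, regeneration, the neuromuscular junction and ribosomal proteins some members rose. None of these lists was called as shifted as a whole (camera adjusted p = 0.92 with an estimated correlation). Without HSALR replicates 9 and 10 the members that rose numbered 4, 3, 2 and 1 in these lists, and 9, 3, 3 and 6 when quantile normalization was applied as well. Of 29 protein folding and unfolded protein response genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone, and 10 and 1 after quantile normalization). Among them were the small heat shock proteins Hspb7 (log2 fold 1.39 ± 0.18) and Cryab (0.36 ± 0.09), Xbp1, a transcription factor of the unfolded protein response (0.69 ± 0.13), and Manf, a stress-induced factor of the endoplasmic reticulum (0.75 ± 0.19). Among 17 regeneration and embryonic muscle genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone). These were Mybph, the cell cycle inhibitor Cdkn1a (0.99 ± 0.18), the myogenic factor Myog (0.85 ± 0.23) and the adhesion molecule Ncam1 (0.61 ± 0.11). Of 23 neuromuscular junction and denervation genes, 4 rose and 0 fell, also adjusted over the list alone (5 and 1 after quantile normalization): Ankrd1, Ncam1, Myog and Lrp4, a receptor of the junction (0.36 ± 0.10). Nfatc2, a transcription factor activated by calcineurin, was the only one of 32 activity and calcineurin responsive genes to rise (log2 fold 1.03 ± 0.14), with 2 adjusted over the list alone. Dimmer probe sets of Nfatc2 had log2 folds of 0.65 ± 0.13, 0.56 ± 0.11 and -0.14 ± 0.10, and the last did not pass (limma adjusted p = 0.473). Of 29 atrophy, ubiquitin ligase and autophagy genes, Fbxo31, an F-box protein, fell (-0.39 ± 0.10), also adjusted over the list alone, and after quantile normalization 2 rose and 6 fell. Of 43 cytosolic ribosomal protein genes, Rps19, Rpl13a and Rpl35 rose by 0.42 ± 0.10, 0.36 ± 0.09 and 0.34 ± 0.09 (15 adjusted over the list alone and 10 after quantile normalization), and none fell.

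**Figure D2:**
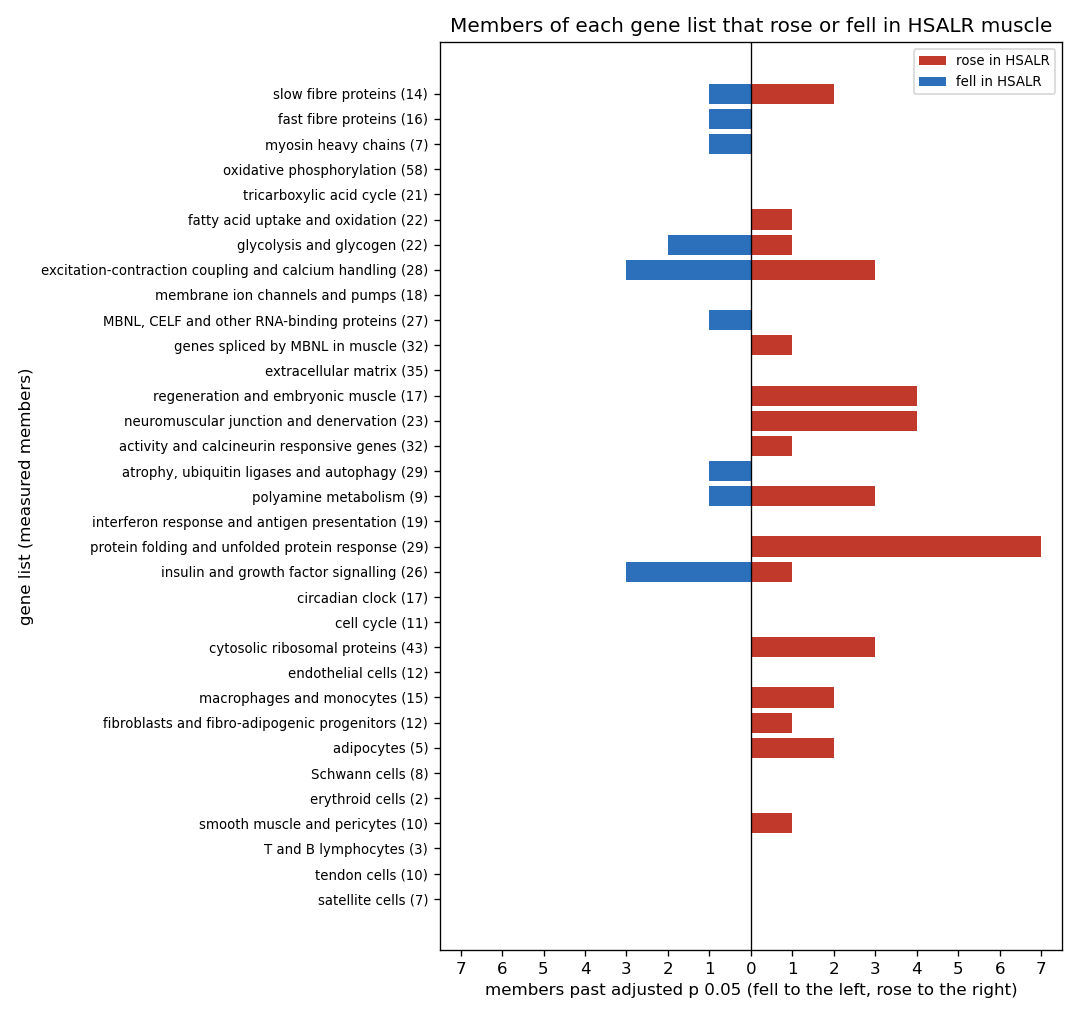
Number of members of each fixed gene list that rose (red, to the right) or fell (blue, to the left) in HSALR muscle at a limma adjusted p under 0.05, with the number of measured members in parentheses. Of 29 protein folding genes 7 rose, and 13 of the 33 lists drawn, which leave out the sex-linked genes, held no changed member.

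Markers of other cells rose in part, and 2 HSALR samples stood apart in them. Of 15 macrophage and monocyte markers, Lgals3 (log2 fold 1.27 ± 0.35) and the lysosomal protein Cd68 (1.00 ± 0.24) rose, against 12 adjusted over the list alone and 5 after quantile normalization. Without HSALR replicates 9 and 10 the log2 fold of Lgals3 was 0.79. The mean of this list lay 1.73 and 1.80 above the wild-type mean (log2, quantile-normalized) in HSALR replicates 9 and 10, against -0.29 to 0.65 in the other 8 HSALR samples. Among 12 markers of fibroblasts and fibro-adipogenic progenitors, the growth factor receptor Pdgfra rose (0.74 ± 0.20), also adjusted over the list alone. In this list replicates 9 and 10 lay 1.28 and 1.24 above the wild-type mean and the highest of the other 8 lay 0.43 above it. None of 35 extracellular matrix genes passed in limma or adjusted over the list alone, with 11 higher and 0 lower at an unadjusted p under 0.05 and 4 higher after quantile normalization. Replicates 9 and 10 lay 1.80 and 1.76 above the wild-type mean, and the other 8 between -0.40 and 0.43. The fat cell hormones Adipoq (1.58 ± 0.41) and Retn (0.69 ± 0.16) rose among 5 adipocyte markers, also adjusted over the list alone. Tagln, an actin-binding protein of smooth muscle (0.52 ± 0.15), rose among 10 smooth muscle and pericyte markers, with 3 adjusted over the list alone, and 3 rose and 1 fell after quantile normalization. No member passed in limma among 10 tendon, 12 endothelial, 8 Schwann cell, 7 satellite cell, 3 lymphocyte and 2 erythroid markers, 19 interferon response, 17 circadian and 11 cell cycle genes. Each gene was read here at its brightest probe set. At a dimmer one Tpx2, of the cell cycle list, fell (log2 fold -1.15 ± 0.16, limma adjusted p = 9.9e-05). In the 13 lists without a changed member, apart from the sex-linked genes, 23 of 221 members were higher and 6 lower at an unadjusted p under 0.05, and adjusted over the list alone 2 satellite cell markers rose. Extracellular matrix genes gave 11 of the 23 that were higher. Over all 22519 tested probe sets 4647 had an unadjusted p under 0.05. These lists were picked for having no member past the threshold, which lowers their share, so the comparison cannot show whether they changed less than others.

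**Figure D3:**
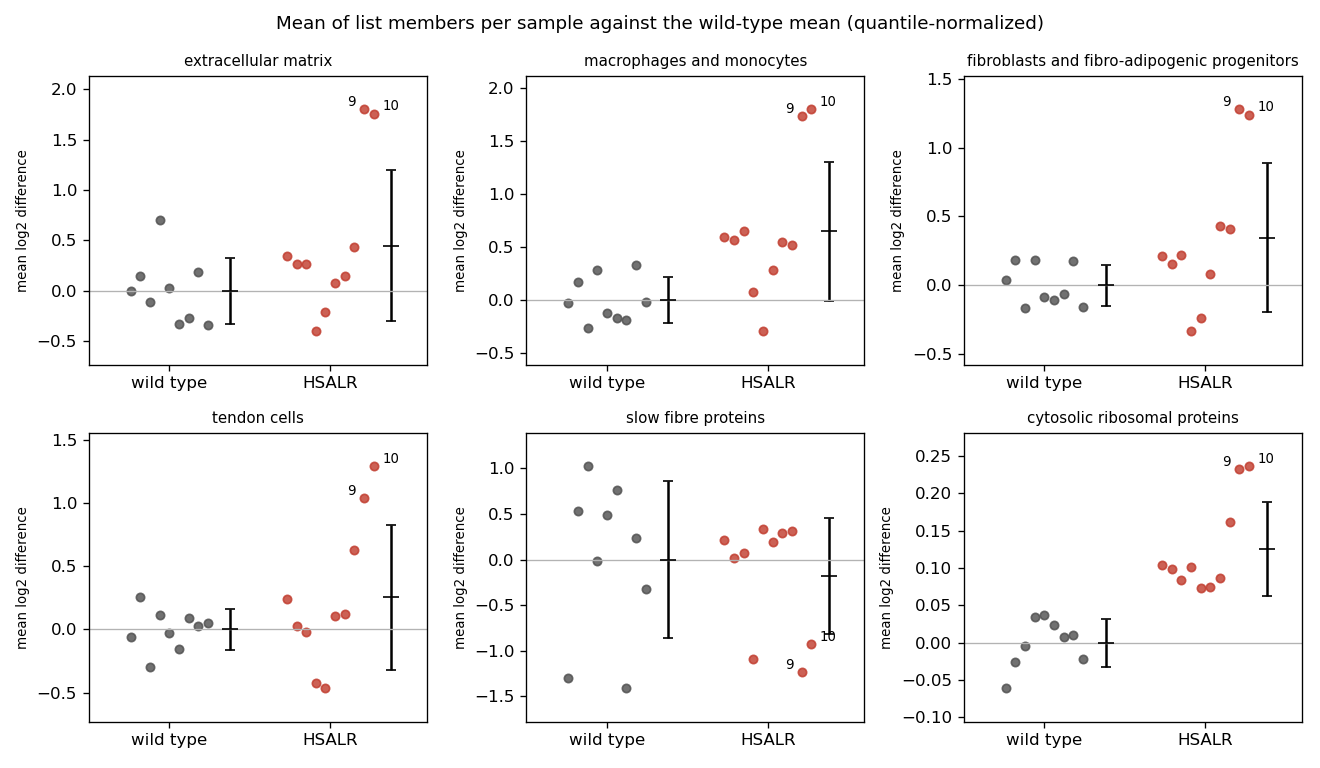
Mean over the members of 6 gene lists of the quantile-normalized log2 signal minus the wild-type mean, 1 point per sample (9 wild-type, 10 HSALR), with the group mean ± SD beside the points. HSALR replicates 9 and 10, marked by number, reach 1.80 and 1.76 for extracellular matrix genes, while the other 8 HSALR samples lie between -0.40 and 0.43.

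As whole lists against all other genes, 0 of 32 lists were called by limma's camera with the correlation between genes estimated from the samples. None had an unadjusted p under 0.05. The macrophage and extracellular matrix lists had mean log2 folds of 0.70 and 0.50 and estimated correlations of 0.875 and 0.809. Their camera p was 0.186 and 0.414, so a count of 0 does not show that no list shifted. Fry's directional test, which compares each list with no change and not with other genes, called 0. With a preset correlation of 0.01, camera called 6 lists, all upward: extracellular matrix, protein folding, cytosolic ribosomal proteins, macrophages, fibroblasts and adipocytes, each with an adjusted p = 0.92 with an estimated correlation. After quantile normalization that setting called 9 lists, of which fast fibre proteins, glycolysis, the tricarboxylic acid cycle and excitation-contraction coupling were shifted downward and adipocytes were no longer called; with an estimated correlation 0 lists passed there too. Without HSALR replicates 9 and 10 it called 4, with extracellular matrix (adjusted p = 0.233) and fibroblasts (0.322) lost. After quantile normalization these replicates lay at -0.35 and -0.38 for the tricarboxylic acid cycle, and the lowest other HSALR sample at -0.14. For glycolysis they lay at -0.29 and -0.31 against -0.18, and for excitation-contraction coupling at -0.155 and -0.24 against -0.06. For fast fibre proteins (-0.13 and -0.13) they lay within the range of the other HSALR samples (-0.20 to -0.025). The members of the ribosomal protein list had a median log2 fold of 0.17, with 0.11 after quantile normalization and 0.11 without replicates 9 and 10. The extracellular matrix list had a median of 0.48, and 0.13 without those replicates. Fry's test for change in either direction called 15 lists, among them excitation-contraction coupling and calcium handling (adjusted p = 1.23e-12). That test also compares each list with no change and does not set it against the changes of other genes. The median, the mean or the direction against other genes differed in sign for the lists of myosin heavy chains, oxidative phosphorylation, the tricarboxylic acid cycle, excitation-contraction coupling, ion channels, insulin signalling, the circadian clock, endothelial cells and Schwann cells. Without HSALR replicates 9 and 10, a setting added after the data were seen, 11 of the named genes missed the threshold, namely Myog, Manf, Pdgfra, Tagln, Azin1, Sat2, Rpl13a, Rpl35, Lrp4, Phkb and Myh7b. The log2 folds of Azin1 (0.45), Myh7b (-0.53), Phkb (-0.30) and Lrp4 (0.34) hardly moved there, while those of Manf and Pdgfra were 0.53 and 0.53. After quantile normalization without the same replicates, Myog (adjusted p = 0.0563) was the only one of these 11 that missed the threshold.

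Probe sets of 1 gene can read different transcript ends, and in some genes they changed by different amounts. Tln1, which links integrins to actin, had a log2 fold of 1.74 ± 0.12 at its dimmer probe set and 0.07 ± 0.11 at its brighter one (limma diffSplice adjusted p = 8.59e-10). Tiam2, an activator of the GTPase Rac, rose at 1 probe set (log2 fold 1.12 ± 0.12) and fell at the other (-0.46 ± 0.11). Cux2 fell at its brighter probe set (-1.93 ± 0.14) and had a log2 fold of -0.11 ± 0.13 at the dimmer one, and the 4 probe sets of Gdap1 ranged from -1.46 to -0.06. Of the 10 probe sets of Meg3, 6 rose, by 0.88 to 2.31 on the log2 scale, and 4 did not pass. Probe sets differed in 90 of 4782 genes with at least 2 tested probe sets, by limma's diffSplice at a false discovery rate of 0.05. The count was 370 after quantile normalization, 333 with arrays centred on their median, 198 with array weights, 165 with no filter on dim probe sets and 52 among the 11260 brightest probe sets.

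**Figure D4:**
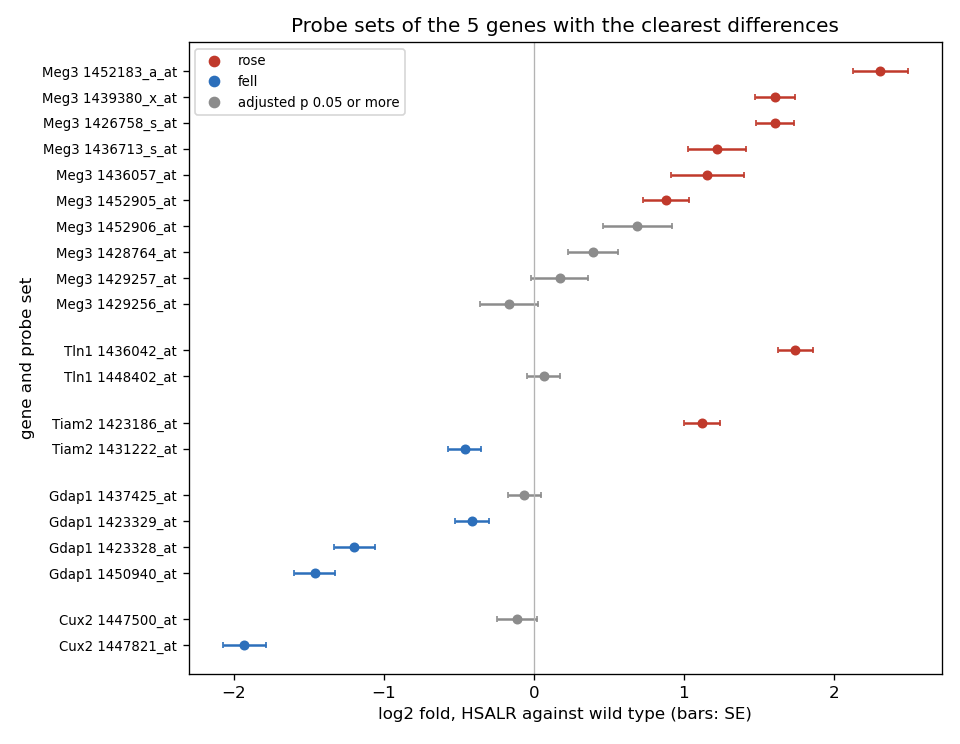
Log2 fold of each tested probe set, HSALR against wild type (bars, SE; 10 against 9 samples), for the 5 genes with the smallest p in the test of differences between probe sets; red and blue mark probe sets that rose or fell, grey those that did not pass. Tiam2 has 1 probe set at 1.12 and another at -0.46.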

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

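Tests chosen only after the result was seen were those of array brightness and of shared RNA for HSALR replicates 9 and 10, the tests of the scaling and of compression between probe sets, and the count of splits for gene lists.

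Single samples lay far from the rest of their group in 12 of 224 group values tested, against 11.2 that chance would give at 1 in 20. In wild type these were the log2 signals of Mmp13 in replicate 4 (5.84, others up to 4.60) and of Acta1 in replicate 6 (13.81, others up to 13.58). On the scale as deposited, the mean of fast fibre proteins reached 0.16 in wild-type replicate 6 and that of regeneration genes was -0.40 in replicate 7. Those of cell cycle genes and smooth muscle markers were 0.30 and 0.39 in replicate 1. After quantile normalization the wild-type SDs of these 4 list means were 0.027, 0.131, 0.043 and 0.123 (n = 9). These are too small for deviations of that size, so part of each went with the scaling. Wild-type replicate 1 also had the highest array median of its group, 7.96 against 7.67 or less. Among HSALR samples, replicate 7 was lowest for Cpne2 (9.48), Acta1 (13.47) and Myh4 (13.52), replicate 3 was highest for Ankrd2 (12.74) and replicate 1 was lowest for Myh2 (12.62).

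Of 100 splits of the 19 samples into groups of 9 and 10, the real one included, only the real one called as many probe sets (1 split; 1140 against at most 4 in any other), as many changed at least 1.5-fold (1 split; 514 against 4) and as many genes whose probe sets differ (1 split; 90 against 2). A random division of the samples thus gave no such counts among the splits drawn. The comparison takes the arrays as independent units, which the labels do not show, and does not tell which single calls are due to chance. For gene lists the real count of 0 is reached by 100 of 100 splits by construction (the highest other was 2), so this count says nothing about chance.

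HSALR replicates 9 and 10 were high in extracellular matrix genes, by a median of 1.72 (log2) over the other 8 HSALR samples, and in macrophage markers, by 1.46, while endothelial markers differed by -0.06 and slow fibre proteins by -0.77. Brightness of the arrays is argued against, since after quantile normalization the lower of both lay 1.329 above the highest other HSALR sample, whose SD was 0.286. Tendon tissue in the samples stays open, because the median excess of 10 tendon markers was 1.092, between the bounds set for and against it (95% bootstrap interval 0.605 to 1.64). Whether 1 animal or RNA was measured on 2 arrays stays open: the SD of their difference was 0.267, against 0.313 for the next closest pair within a group, but the pair was singled out for its likeness, so this decides nothing, and a shared handling or response of different animals was not tested. The labels put both in the HSALR group and give no reason for either to differ.

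More probe sets passed after the arrays were brought to 1 distribution. A difference in brightness between the groups is argued against as the cause, since removing only the group difference of the array medians gave 1208 probe sets, against 1140 as deposited and 3340 after quantile normalization. Brightness that varies within the groups is a candidate explanation, since removing only that spread gave 3240, and the median residual SD fell by 17.3% after quantile normalization, from 0.276 to 0.228. Whether amounts of RNA truly varied between the muscles was not tested.

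In 90 genes the probe sets changed by different amounts. Array brightness as the cause is argued against, since 90 of 90 were also called after quantile normalization, while 58 were called without HSALR replicates 9 and 10. Compression at the brightness of the probe set with the smaller change was examined in all 90. For 76, at least 3 probe sets of other genes, brighter than that one in both groups, changed as much as the gene's larger change. This argues against compression only in those of the 76 whose larger change lay in the dimmer probe set. In the 37 genes where it lay in the brighter one, compression of the brighter probe set could not arise, so the test was empty. For the other 14, Ckm and Myh1 among them, this test did not decide, as fewer than 3 such probe sets were found (2 for Tln1). In each of these 14 the larger change lay in the dimmer probe set, as compression would give. In 2 of the 90, Tiam2 and Reep5, a probe set rose and another fell, too few genes to decide about compression. The larger change lay in the dimmer probe set in 53 genes and in the brighter in 37 (binomial p = 0.113), which also left it undecided. Limits of single probes and signal near background were not tested, and a difference in transcript structure between HSALR and wild type, which the genotype could bring, stays open.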

How the results depend on the processing

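Leaving out HSALR replicates 9 and 10, averaging them, and leaving them out with quantile normalization were chosen after the data were seen; the other settings were planned. The number of changed probe sets (1140) stayed within 1.5 times under both pseudocounts, both filters, the other variance model and without or with averaged HSALR replicates 9 and 10 (829 and 942), but was 3340 after quantile normalization, 2937 with arrays centred on their median, 2490 after quantile normalization without those replicates, 2878 with array weights, 2169 with the 3'/5' ratio as a covariate and 176 in the test against a fold of 1.2. Fits without 1 sample gave 858 to 2067, and the highest, without HSALR replicate 5, the dimmest array, was the only one beyond 1.5 times. Changes of at least 1.5-fold (514) numbered 336 with a pseudocount of 64, which shrinks folds of dim genes, 307 among the 11260 brightest probe sets, where fewer were tested, 1208 with the 3'/5' covariate and 451 to 779 without 1 sample, the highest again without HSALR replicate 5. Genes whose probe sets differ (90) numbered 165 without a filter and 52 among the 11260 brightest probe sets, as more or fewer were tested, 370 after quantile normalization, 333 with arrays centred, 198 with array weights, 309 after quantile normalization without HSALR replicates 9 and 10, and 64 to 105 without 1 sample. Shifted lists (0) numbered 6 with a preset correlation, 0 without any 1 sample and 0 under each other setting. Apart from what is stated, the cause was not tested.

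With the replicate number as a replicate block 716 probe sets passed (409 higher, 307 lower), and 456 changed at least 1.5-fold, 0 lists and 68 genes whose probe sets differ. HSALR replicate 10, whose number no wild-type sample has, was left out of this fit. Leaving out that replicate without a block gave 956 probe sets. The labels do not say that equal numbers mark pairs: deviations of samples with the same number correlated by -0.23 to 0.12, and 1 of 9 wild-type samples was closest to its own number.

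The log2 fold of Acta1 (0.03) reversed to -0.0105 after quantile normalization, -0.0286 with arrays centred and -0.0164 after quantile normalization without HSALR replicates 9 and 10, and ranged from 0.0152 to 0.0549 without 1 sample. That of Dmpk (-0.05) reversed to 0.0516 with array weights and ranged from -0.1055 to 0.0226 without 1 sample, the highest without wild-type replicate 1. Myh4 (0.01) reversed to -0.0179 after quantile normalization, -0.042 with arrays centred and -0.0226 after quantile normalization without HSALR replicates 9 and 10, and ranged from -0.001 (without HSALR replicate 8) to 0.0311 without 1 sample. Myh1 (0.04) reversed to -0.0177 with arrays centred, Myh2 (-0.01) ranged from -0.0544 to 0.0571 (without HSALR replicate 1) without 1 sample, and the brightest probe set of Tln1 (0.07) reversed to -0.0165 with the 3'/5' covariate; none of these passed in any of the settings named. The mean 3'/5' difference of -0.05 ranged from -0.0579 to -0.0367 without 1 sample, and its exact permutation p passed 0.05 without wild-type replicate 1 or 4 or HSALR replicate 4 or 5 (highest p = 0.0633). Under settings other than leaving out 1 sample, 864 values of named genes other than Acta1 and Dmpk kept their direction and side of the threshold, 57 lost and 6 gained the call and 5 reversed. Of 64 named genes past the threshold, 12 missed it in at least 1 of 19 fits without 1 sample (highest adjusted p = 0.0943): Phkb in 16, Tagln, Azin1 and Lrp4 in 13, Cd36 in 12, Myog and Fbp2 in 10, Lgals3 and Myh7b in 9, Pdgfra in 5, Mmp3 in 2 and Fbxo31 in 1. The Xist covariate was not run, since the Xist signal spanned 1.07 (log2), below the 2 required. Signal near background limits all counts to the 22519 brighter probe sets.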

Other observations

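The tests of p53 targets and of imprinted genes were chosen after Eda2r, Cdkn1a, Meg3 and Rian had been seen, and the genes in the next 2 paragraphs were also chosen after their values were seen.

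Several single genes outside the fixed lists rose in HSALR muscle, and no group was tested for them. Sntb1, a syntrophin of the dystrophin complex, rose 3.06-fold (log2 fold 1.61 ± 0.23, SE, limma adjusted p = 9.74e-05), Mustn1, a small nuclear protein of muscle and bone, 3.18-fold (1.67 ± 0.20) and Tubb6, a beta tubulin, 3.02-fold, in each case above all wild-type samples in 10 of 10 HSALR samples. The other probe set of Tubb6 had a log2 fold of -0.10 ± 0.12 (limma adjusted p = 0.671). The Z-disc and thin filament genes Flnc (0.84 ± 0.14), Xirp1 (1.01 ± 0.20) and Lmod2 (0.71 ± 0.17) and the M-band gene Myom3 (0.67 ± 0.14) also rose. Uchl1, a ubiquitin hydrolase of nerve and stressed muscle, rose by 1.32 ± 0.14, and Agrn, which encodes agrin, the organiser of acetylcholine receptor clusters, by 1.30 ± 0.23. The monocyte genes Mpeg1 (1.28 ± 0.36) and Ccl6 (1.16 ± 0.30) rose with all samples, but had adjusted p of 0.112 and 0.0541 without HSALR replicates 9 and 10.

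Other single genes outside the lists fell, again without a test of any group. Prkag3, the muscle-specific gamma subunit of the AMP-activated kinase, had a log2 fold of -0.75 ± 0.10 (limma adjusted p = 7.56e-05), beside the -0.73 of its partner Prkab2, and all 10 HSALR samples lay below every wild-type sample for Prkag3. Me1, malic enzyme, had a log2 fold of -1.07 ± 0.14, Slc37a4, the glucose 6-phosphate transporter, of -0.96 ± 0.14 and Gpd2, the mitochondrial glycerol phosphate dehydrogenase, of -0.56 ± 0.11. The potassium channel genes Kcng4 and Kcnn4 had log2 folds of -0.93 ± 0.15 and -0.82 ± 0.20, and Acvr2a, an activin and myostatin receptor, of -1.04 ± 0.10. Each of these 7 genes also passed after quantile normalization and without HSALR replicates 9 and 10. The 2 probe sets of Acvr2a changed by different amounts (limma diffSplice adjusted p = 0.04).

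Eda2r and Cdkn1a are targets of the transcription factor p53, and the hypothesis that p53 targets rose as a set was tested on 15 other targets. Camera with an estimated correlation on quantile-normalized values gave p = 0.341, and 4 of the 15 rose and 2 fell, with a median log2 fold of 0.05. As deposited 1 rose, Phlda3, and 2 fell, and after quantile normalization without HSALR replicates 9 and 10 Phlda3 passed, while Trp53inp1 (adjusted p = 0.129), Zmat3 (0.125) and Bbc3 (0.054) missed the threshold with log2 folds of 0.44, 0.16 and 0.33, against 0.64, 0.20 and 0.31 with those replicates. In that setting 3 targets were lower, Ddit4l (adjusted p = 0.000102), Polk (0.000297) and Apaf1 (log2 fold -0.30, 0.0121), which goes against a rise of the set. Phlda3 rose (log2 fold 0.85 ± 0.10) and Ddit4l fell (-0.54 ± 0.09), while Mdm2, a main p53 target, had a log2 fold of -0.004 ± 0.17. The values leave the hypothesis open: a few targets may have changed without the set.

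Meg3, Rian and, at 1 of its probe sets (log2 fold 2.03 ± 0.24), Mirg rose, which lie in 1 imprinted cluster. Whether imprinted genes changed in general stays open. As deposited 0 of 25 imprinted genes outside the cluster passed, where 1.36 were expected from the 5.43% of other genes (Fisher's exact p = 1, 1-sided, which a count of 0 fixes), and the upper 95% limit of their share, 11.3%, is above that of other genes. Grb10 was lower without HSALR replicates 9 and 10 (log2 fold -0.55, adjusted p = 0.0105). Copg2 and Cd81 were higher after quantile normalization (log2 folds 0.30 and 0.23, limma adjusted p = 0.0164 and 0.0485). The brightest probe set of Mirg missed the threshold (log2 fold 0.49 ± 0.16, limma adjusted p = 0.0679). Whether the cluster is transcribed more or its RNA is more stable was not tested.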
